A study of Homo sapiens with 32 samples.

How the data were processed

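The series holds 32 SLAM-seq libraries from HCT116 cells: 4 siRNA conditions (siControl, siIGF2BP2, siIGF2BP3 and both targeting siRNAs, the double knockdown) by 2 treatments (DMSO or tunicamycin), with 4 libraries in each of the 8 groups. Groups were taken from the labels. Replicate numbers 1 to 4 recur in every group, and the labels do not say what they mark.

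The deposited tables hold 1 row for the 3′ UTR of each RefSeq transcript, 95582 rows per library, aligned by the authors to the human genome hg38. Per the file headers they hold read counts: all reads over the 3′ UTR and reads with T-to-C changes, which were used here as deposited, with no normalization by the authors. Counts scaled to 1e6 reads per library (CPM) are also deposited by the authors; they equal each read count divided by the column total, were not used in any test, and CPM values printed here were recomputed over the genes kept, with TMM-scaled library sizes. Conversions and covered T positions per 3′ UTR, as deposited, gave the percent of converted T per library. The column for multiply mapped reads is 0 throughout, so how such reads were treated is not visible in the files.

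Transcript rows were named with the RefSeq table of GRCh38.p14 (46328 rows) and GENCODE release 29 (397 rows); 48857 rows were not named, of which 21749 carried no accession in these tables. For each of 19000 named genes the transcript row with the most reads over all libraries was kept; 15276 genes had reads, and 72 of them, with counts identical to another gene's in every library, were dropped, leaving 15204. Each library then held 4459593 to 13146136 reads. Genes annotated with the same 3′ UTR, such as read-through transcripts, share reads in these tables. Whether genes of merely similar sequence do so is not visible.

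The 3 measures were tested with edgeR 4.0.16 (R 4.3.3), with quasi-likelihood F tests, trimmed-mean (TMM) scaling and the Benjamini-Hochberg adjustment over all genes of a comparison, at an adjusted p of 0.05. They are total RNA (all reads, 11888 genes), labelled RNA (reads with T-to-C changes, 10459 genes) and labelled share (labelled against unlabelled reads, 10428 genes). Genes were kept by edgeR's filter on low counts by group. All 32 libraries entered 1 fit per measure, so all groups share 1 estimate of the spread of a gene, however much their own libraries vary. For the share, the labelled and the unlabelled reads of a library formed 2 columns with a term per library, each kind scaled within itself. The fitted log2 change is thus that of the labelled to unlabelled ratio relative to the typical gene. Standard errors are the fitted log2 change divided by the square root of F. Comparisons planned before the files were seen were tunicamycin against DMSO in siControl, each knockdown against siControl under DMSO and under tunicamycin, and the 3 interactions of knockdown with tunicamycin. Tunicamycin against DMSO within each knockdown was added after the data were seen. The percent of labelled reads per library was compared with an exact permutation test.

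Precision was tested on simulated data built from the files, with the total reads of 200 genes and the labelled share of 200 others changed in each of 2 comparisons. Labelled RNA changes in both sets, and its recovery is given over the former. A log2 change of 1 was recovered in 63 to 64% of genes for total RNA, 46.5 to 51.5% for labelled RNA and 78 to 85.9% for labelled share, and a change of 2 in 92% or more for each. In each run 6 to 16 unchanged genes were called. The simulated genes varied independently, without deviations common to many genes of a library and without an outlying library. These rates may thus not hold for the real libraries. Libraries of the same group differed by more than read sampling in every pair (chi-square per gene 6.21 to 287.71).

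Genes were named by a rule fixed beforehand: IGF2BP1, IGF2BP2 and IGF2BP3 always, and, per comparison and measure, the largest log2 changes in each direction (10 for total RNA after tunicamycin in siControl, 5 elsewhere). The latter had to be past the threshold, with a mean of at least 10 CPM over the libraries compared and with no overlap between the libraries of the 2 groups. Members of a gene list are named beside the list, smallest p first, and a gene named once may be given elsewhere. In all, 33 gene lists were fixed beforehand and tested with limma's camera (limma 3.58.1; preset correlation between genes of 0.01, at least 5 measured genes), adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. Counts adjusted over the list alone use the adjustment over the list members only.

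Replicate numbers were checked for pairing by the correlation of deviations from the group means. Libraries with the same number correlated above 0.1 in all 4 pairs in 2 comparisons, siIGF2BP3 against siControl under DMSO (0.139 to 0.601) and tunicamycin against DMSO after siIGF2BP2 (0.366 to 0.746). In each, only 2 of the 4 numbers correlated best with their own. For instance, siIGF2BP3 replicate 1 correlated at 0.392 with siControl replicate 3 and at 0.139 with replicate 1. Likewise, siIGF2BP2 tunicamycin replicate 1 correlated at 0.765 with DMSO replicate 2 and at 0.366 with replicate 1. Pairing by number is thus not established. In the second comparison, however, numbers 1 and 2 deviated together, as did 3 and 4 (0.331 to 0.765). Between these sets every correlation was negative (-0.818 to -0.343). Asking for the best match by number cannot detect a batch that spans 2 numbers. With the replicate number as a block these 2 comparisons gave 8 genes against 7 and 421 against 450.

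Agreement between knockdowns was compared with 20 simulated unchanged groups sharing the same controls, and with the control libraries split between the comparisons in all 6 ways. Alternatives tried were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, the replicate number as a block, a fit of only the groups compared, scaling of labelled reads by total reads, and leaving out each library in turn. Added after the data were seen were the transcript row with the longest 3′ UTR, a correction for the GC percent of the last 500 bases of the transcript (spline with 5 degrees of freedom), and separate mention of siControl tunicamycin replicate 3. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.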

Results

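SLAM-seq libraries were made from HCT116 cells, an established human colorectal carcinoma line, to follow RNA amounts and RNA turnover when IGF2BP2, IGF2BP3 or both are knocked down, with and without endoplasmic reticulum (ER) stress. IGF2BP2 and IGF2BP3 are RNA-binding proteins that bind many mRNAs and affect their stability. Cells received 75 nM siRNA for 48 h: a non-targeting control (siControl), siIGF2BP2, siIGF2BP3 or both. Tunicamycin (5 µg/mL, 4 h), which blocks N-linked glycosylation and so causes protein misfolding in the ER, was the stressor, and DMSO the vehicle. The nucleoside 4-thiouridine (s4U, 250 µM) was present for the last 2 h, so RNA made in that time can carry T-to-C changes in its sequencing reads (labelled reads). Reads of such RNA without a change count as unlabelled. Per library 0.65 to 1.43% of covered T were converted. Every library had s4U, so the background of T-to-C changes in older RNA is not known. Labelled and unlabelled reads thus only approximate new and older RNA. The design has 8 groups of 4 libraries; expression levels are counts scaled to 1e6 reads per TMM-scaled library size (CPM). After assignment to genes, the libraries held 4459593 to 13146136 reads, and 11888 genes had enough reads to test for total RNA. The labels do not say whether the 4 replicates are separate cultures, so all p-values measure only the spread between these samples, which may be technical.

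Knockdown was visible in every targeted comparison. IGF2BP2 (chromosome 3, 185643130 to 185825042, GRCh38; counted over a 3′ UTR of 1792 bases) stood at 284.5 ± 9.74 CPM (SD, n = 4) in siControl cells under DMSO. It stood at 93.8 ± 13.6 CPM after siIGF2BP2 and at 85.7 ± 14.3 CPM after the double knockdown, leaving 33% and 30.1% of the control level by the fitted fold change. Under tunicamycin it stood at 421.7 ± 203.8 CPM in siControl, where replicate 3 alone reached 724.1 CPM. The knockdowns had 129.3 ± 35.6 CPM after siIGF2BP2 (30.7%) and 110.6 ± 14.1 CPM after the double knockdown (26.3%). Without siControl tunicamycin replicate 3 these log2 changes went from -1.71 to -1.31 and from -1.93 to -1.54, so more IGF2BP2 remained. IGF2BP3 (chromosome 7, 23310209 to 23470491; 3′ UTR of 2153 bases) fell from 118.3 ± 10.9 CPM to 40.8 ± 5.93 CPM after siIGF2BP3 (34.4%) and to 46.2 ± 4.59 CPM after the double knockdown (39.1%) under DMSO. Under tunicamycin it fell from 139.1 ± 33.0 CPM to 35.5 ± 4.30 CPM (25.5%) and 48.0 ± 4.99 CPM (34.6%). All 8 of these tests passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, with adjusted p from 3.81e-08 to 0.000141, and passed it again with any 1 of the compared libraries left out. With only the groups compared in the fit 4 of the 8 passed, those under DMSO, while under tunicamycin no gene did. Neither siRNA changed the other paralog past the threshold. The largest difference was IGF2BP2 after siIGF2BP3 under tunicamycin, at 63.9% of its control (adjusted p = 0.0912). That control includes replicate 3 at 724.1 CPM. Its other libraries stood at 281.7 to 355 CPM, against 260.9 to 278 CPM after siIGF2BP3. IGF2BP1, the remaining family member, did not exceed 1.61 CPM in any library.

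**Figure D1:**
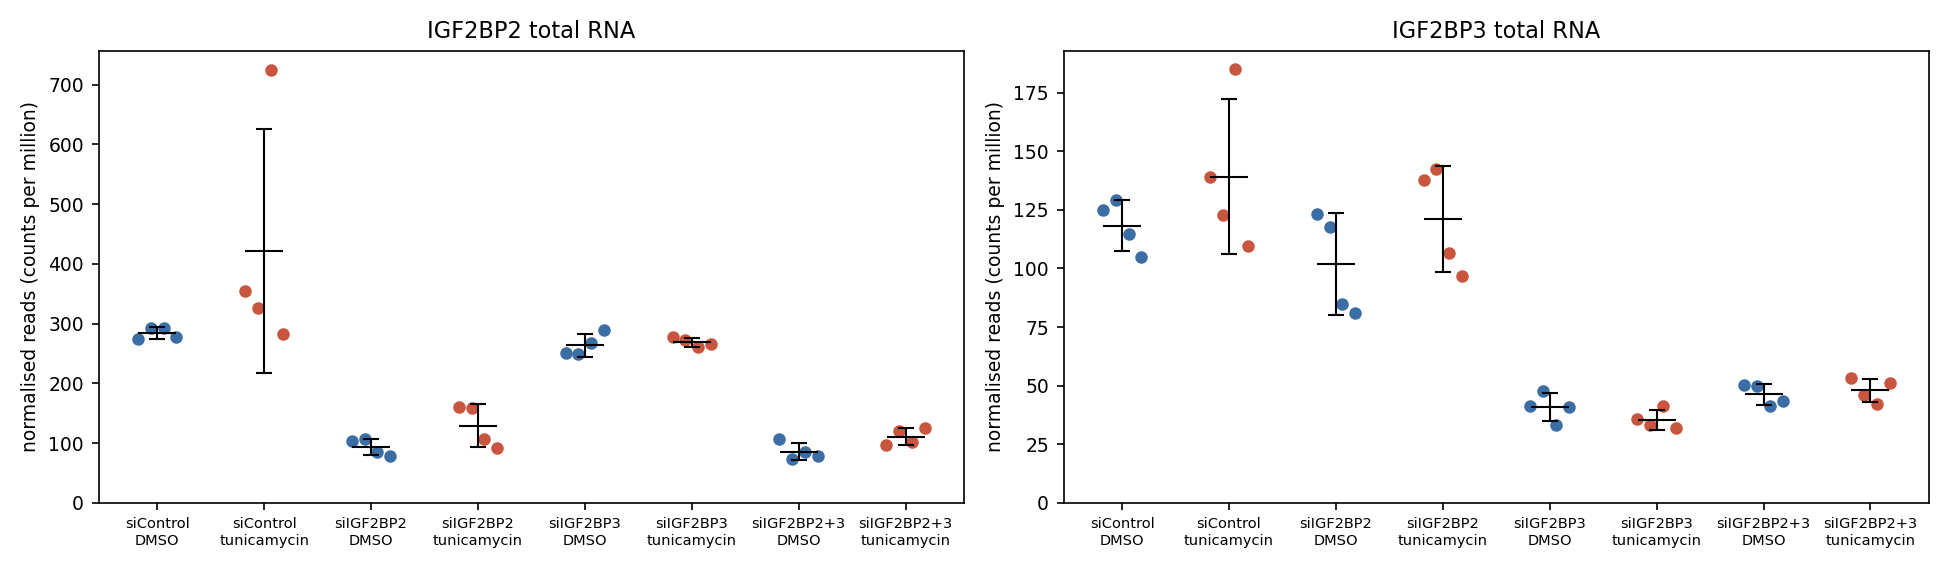
Total RNA of IGF2BP2 (left) and IGF2BP3 (right) in CPM for the 4 libraries of each of the 8 groups (blue, DMSO; red, tunicamycin), with mean and SD as black bars. Groups given the matching siRNA lie below siControl, for instance 93.8 against 284.5 CPM for IGF2BP2 and 40.8 against 118.3 CPM for IGF2BP3 under DMSO, and siControl tunicamycin replicate 3 stands apart at 724.1 CPM for IGF2BP2.

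Labelling differed between groups. In siControl cells 15.09 ± 0.33% of reads were labelled under DMSO and 13.25 ± 0.89% under tunicamycin, a difference of -1.85 points (2-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give; p = 0.0571 without siControl DMSO replicate 1). T-to-C conversions per covered T followed, at 1.367 ± 0.058% and 1.036 ± 0.063%. The knockdown groups under DMSO had 13.28 ± 0.40% (siIGF2BP2), 14.30 ± 0.40% (siIGF2BP3) and 14.29 ± 0.30% (double) labelled reads, and under tunicamycin 10.76 ± 0.09%, 12.29 ± 0.60% and 11.86 ± 0.60%. Because the fits scale labelled and unlabelled reads separately, every change in labelled RNA or labelled share below is relative to the typical gene of the same library. For genes with a high labelled share this may leave part of the overall difference in. The median share change of the 10% of genes with the highest labelled share in siControl under DMSO was -0.545 after tunicamycin in siControl and -0.401, -0.295 and -0.287 after the knockdowns under DMSO, against -0.039, 0.004, 0.017 and 0.003 over all genes. The libraries used to choose these genes are also the reference there, so part of the fall can come from the choice. After the knockdowns under tunicamycin, with another reference, the same genes had medians of -0.144, -0.145 and -0.161. Scaling by total reads instead moved the median of all genes after tunicamycin in siControl by -0.29 (log2) for labelled RNA and -0.39 for labelled share.

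**Figure D2:**
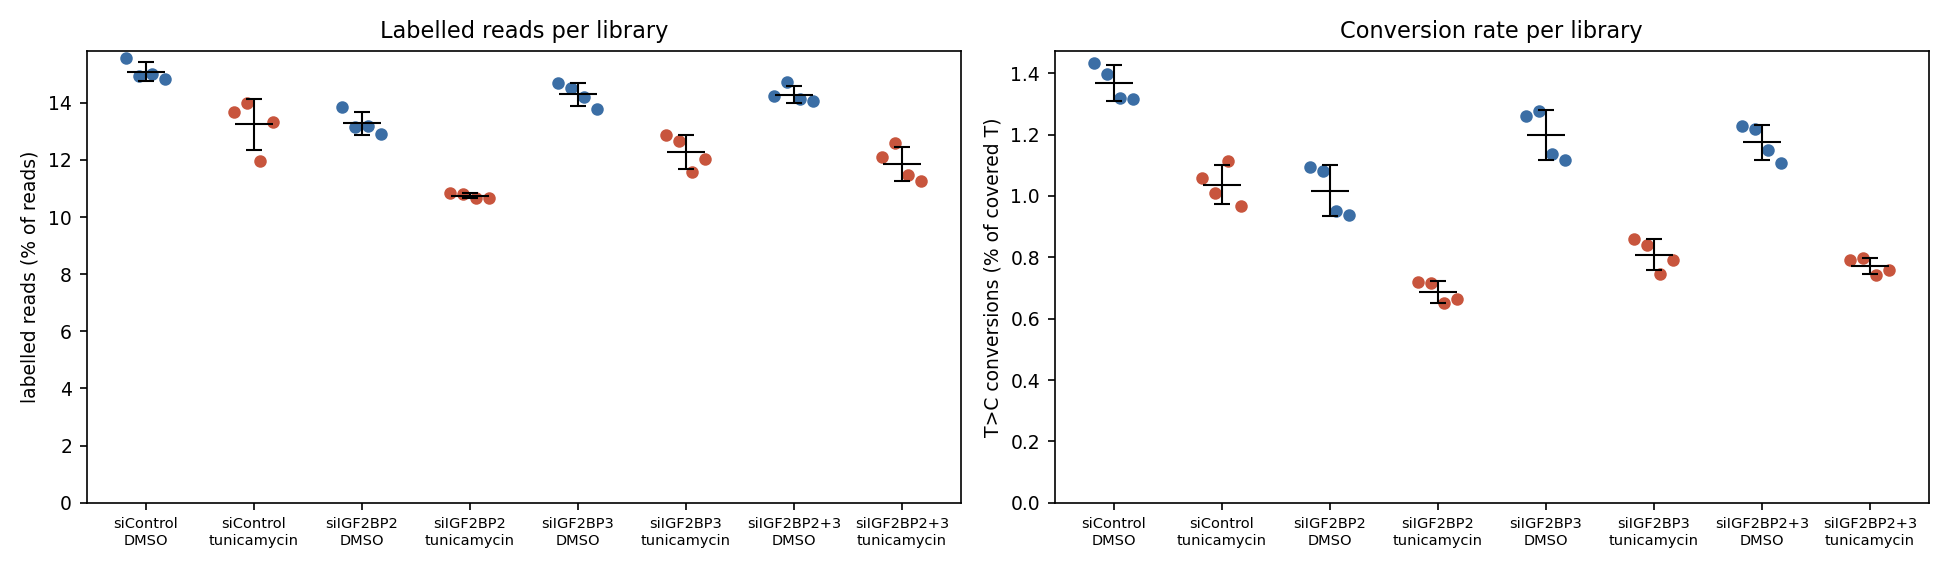
Percent of reads with T-to-C changes (left) and T-to-C conversions as percent of covered T (right) for the 4 libraries of each group (blue, DMSO; red, tunicamycin), with mean and SD as black bars. Each tunicamycin group has a lower mean than the DMSO group with the same siRNA, for instance 13.25% against 15.09% labelled reads in siControl.

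Tunicamycin in siControl cells raised the classical ER stress genes. Among the 10 genes with the largest increase in total RNA were DDIT3, the pro-apoptotic transcription factor CHOP (chromosome 12, 57516588 to 57520517; log2 change 5.58 ± 0.26 SE, adjusted p = 2.16e-15), and CHAC1, a glutathione-degrading enzyme (5.12 ± 0.30, adjusted p = 2.49e-13). So were HERPUD1, a component of ER-associated degradation (4.31 ± 0.26, adjusted p = 3.82e-13), and the stress-induced mTORC1 inhibitors SESN2 (3.91 ± 0.24) and DDIT4 (3.55 ± 0.21). FICD, which AMPylates the ER chaperone BiP (4.55 ± 0.54), TMEM125 (3.64 ± 0.39), ADM2 (3.52 ± 0.40), JDP2 (3.44 ± 0.37) and SDF2L1 (3.18 ± 0.35) completed that group. The 10 largest decreases were HSPA1B, an inducible cytosolic HSP70 (-2.65 ± 0.44, adjusted p = 0.000109), ARL4C (-1.89 ± 0.30), TNS4, a focal adhesion protein (-1.75 ± 0.23, adjusted p = 4.32e-06), the phosphatase DUSP2 (-1.71 ± 0.45) and 6 others. These were DIPK2A (-1.57 ± 0.32), the ephrin EFNA3 (-1.51 ± 0.37), TMEM64 (-1.43 ± 0.37), METRNL (-1.43 ± 0.36), the WNT coactivator BCL9 (-1.42 ± 0.32) and the Polycomb protein CBX2 (-1.42 ± 0.30). Ranks here and below leave out genes with a mean under 10 CPM over the libraries compared and genes for which the libraries of the 2 groups overlapped, some with larger changes. All 20 genes named here kept their call with any 1 of the 8 libraries left out. Without siControl tunicamycin replicate 3 the change was smaller for FICD (3.40), TMEM125 (2.75), JDP2 (2.75) and SDF2L1 (2.49).

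Gene lists fixed before the data were examined moved as groups (edgeR per gene, camera per list). Of 28 measured genes of the PERK-ATF4 branch of the unfolded protein response 21 rose and none fell (25 adjusted over the list alone; median log2 change 1.80, camera adjusted p = 2.83e-35). TRIB3 (2.88 ± 0.16) and the cystine transporter SLC7A11 (3.01 ± 0.24) were among them. ER chaperones rose in 14 of 20 (15 adjusted over the list alone; median 1.38, adjusted p = 1.53e-20), led by HSPA5, which encodes BiP (2.85 ± 0.14), and DNAJC3 (2.21 ± 0.15). XBP1 targets and ER-associated degradation genes rose in 16 of 23 (17 adjusted over the list alone; median 1.15, adjusted p = 3.23e-22), including SEL1L (2.76 ± 0.15) and XBP1 itself (1.76 ± 0.12). Cytosolic tRNA synthetases rose in 8 of 20 (9 adjusted over the list alone; median 0.33, adjusted p = 2.33e-06), with GARS1 at 1.28 ± 0.14. Genes of N-glycan precursor synthesis, the pathway tunicamycin blocks, rose in 6 of 26 (8 adjusted over the list alone; median 0.28, adjusted p = 0.00158), with GFPT1 at 1.53 ± 0.14. Of 18 reported targets of nonsense-mediated decay 7 rose and 1 fell, the same numbers adjusted over the list alone (median 0.23, adjusted p = 0.00112). The members that rose first were GADD45A, CARS1, ATF3 and ATF4, which are themselves stress-response genes. Immediate early genes rose in 7 of 23, among them DUSP6 (1.45 ± 0.15), EGR1 (1.57 ± 0.17) and JUN (1.35 ± 0.17), and fell in 1. Adjusted over the list alone 7 rose and 2 fell (median 0.44, adjusted p = 0.00295, and adjusted p = 0.144 with an estimated correlation).

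Other lists moved down. Of 10 reported substrates of IRE1-dependent mRNA decay 4 fell, the same number adjusted over the list alone (median -0.20, camera adjusted p = 0.00222): CD59 (-1.26 ± 0.12), PMP22 (-1.21 ± 0.17), DGAT2 (-4.45 ± 0.77) and BLOC1S1 (-0.66 ± 0.15). Heat shock genes fell in 2 of 16, HSPA1B and HSPE1, also 2 adjusted over the list alone (median -0.36, adjusted p = 0.00158). WNT and colon stem cell genes fell in 5 of 15 (6 lower and 3 higher adjusted over the list alone; median -0.24, adjusted p = 0.0398, and adjusted p = 0.0594 with an estimated correlation). AXIN2 (-2.34 ± 0.42), SOX9 (-0.83 ± 0.16) and RNF43 (-1.07 ± 0.28) were among them. Reported IGF2BP target mRNAs fell in 5 of 29 (6 lower and 1 higher adjusted over the list alone; median -0.23, adjusted p = 0.0245, and adjusted p = 0.0875 with an estimated correlation). FSCN1 stood at -0.64 ± 0.11 and CCND1 at -0.77 ± 0.16. Mitotic genes fell in 2 of 25, CKS2 and BIRC5, and in 0 adjusted over the list alone (median -0.29, adjusted p = 0.0035, and adjusted p = 0.205 with an estimated correlation). In the respiratory chain list 1 of 33 rose and 2 fell (1 and 1 adjusted over the list alone; adjusted p = 0.0248, and adjusted p = 0.213 with an estimated correlation). Apoptosis regulators (5 of 21 higher, adjusted p = 0.139), autophagy genes (4 of 20 higher, adjusted p = 0.141) and cholesterol synthesis genes (5 higher and 3 lower of 23, adjusted p = 0.619) did not pass as lists. Of the marker lists for other cell types, 2 leukocyte and 4 fibroblast genes were measured and 0 of them passed the threshold in edgeR.

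In all, 1588 of 11888 genes passed after tunicamycin in siControl (1136 higher, 452 lower), 793 of them by at least 2-fold. Replicate 3 of siControl under tunicamycin stood apart from its group, with a median correlation with the other 3 libraries of 0.691 against 0.893 to 0.922 for those. Its 10 most abundant genes took 11.45% of its reads against 5.47 to 6.19%, and GAPDH, picked after its values were seen, stood at 53160 CPM in it against 12108, 4907 and 6710 CPM in replicates 1, 2 and 4. Replicate 1 differed from replicates 2 and 4 as well (chi-square per gene 71.92 and 54.99, against 7.27 between those 2). Without siControl tunicamycin replicate 3, 818 genes passed (496 higher, 322 lower), of which 684 were shared with the full set. The count also moved to 930, 928 and 950 without siControl DMSO replicates 1, 3 and 4, and to 2685 and 2434 without siControl tunicamycin replicates 2 and 4. With only these 8 libraries in the fit 97 genes passed, and a correction for GC content gave 1577 with a split of 974 higher to 603 lower. Without replicate 3 the ER stress lists kept their calls: PERK-ATF4 genes rose in 23 of 28 and ER chaperones in 14 of 20.

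**Figure D3:**
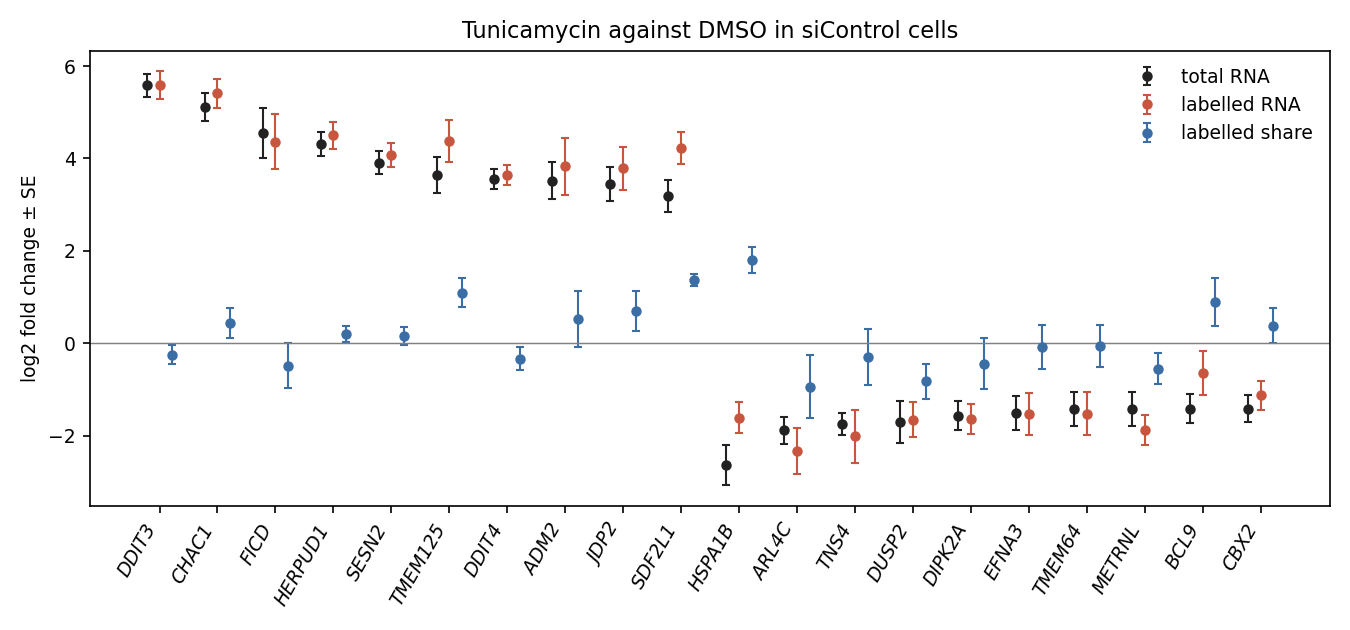
Log2 change with SE after tunicamycin against DMSO in siControl for the 10 genes with the largest increase and the 10 with the largest decrease in total RNA, of those at 10 CPM or more with no overlap between the groups (black), with their labelled RNA (red) and labelled share (blue). Total and labelled RNA moved together for DDIT3 (5.58 and 5.59) and CHAC1 (5.12 and 5.41), while HSPA1B had less total RNA (-2.65) and a higher labelled share (1.80).

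The same treatment was compared within each knockdown, a comparison added after the data were seen. DDIT3 rose by 5.49 (log2) after siIGF2BP2, 5.12 after siIGF2BP3 and 5.30 after the double knockdown. In the same order HERPUD1 rose by 4.54, 4.60 and 4.77, CHAC1 by 4.21, 4.26 and 4.42 and DDIT4 by 3.55, 3.58 and 3.89 (SE 0.21 to 0.29, n = 4 per group). PERK-ATF4 genes rose in 19, 21 and 22 of 28 measured members (24, 24 and 25 adjusted over the list alone; camera adjusted p = 1.34e-45, 6.74e-44 and 1.66e-46). ER chaperones rose in 12, 12 and 13 of 20 (15, 16 and 17 adjusted over the list alone) and XBP1 and ER-associated degradation genes in 15, 14 and 15 of 23 (17, 19 and 21 adjusted over the list alone). LRFN1 (-1.58 ± 0.22, -1.52 ± 0.22 and -1.71 ± 0.23) and TNS4 (-1.21 ± 0.24, -1.46 ± 0.23 and -1.95 ± 0.24) fell in all 3 knockdowns. In all, 450 genes passed after siIGF2BP2 (324 higher, 126 lower), 574 after siIGF2BP3 (327 and 247) and 516 after the double knockdown (327 and 189). With only the 8 libraries compared the counts were 290, 1543 and 733, and the siIGF2BP3 count moved to 355 without its DMSO replicate 2 and to 345 and 365 without its tunicamycin replicates 1 and 2. Whether the response differed between knockdown and control was tested as an interaction, given at the end.

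In labelled RNA, taken as made in the last 2 h, the ER stress lists rose as well. DDIT3 (5.59 ± 0.30, adjusted p = 4.59e-17), CHAC1 (5.41 ± 0.31), HERPUD1 (4.50 ± 0.29) and TMEM125 (4.39 ± 0.46; 3.60 without siControl tunicamycin replicate 3) were among the increases. The call of ACAP1 rests on 1 labelled read over the DMSO libraries and 21 over the tunicamycin libraries, and was lost without siControl DMSO replicate 1, 2 or 3 (adjusted p up to 0.102). ER chaperones rose in 19 of 20 (also 19 adjusted over the list alone; median 2.80, camera adjusted p = 7.01e-46), with HSPA5 at 4.01 ± 0.16 and CRELD2 at 3.81 ± 0.23. PERK-ATF4 genes rose in 23 of 27 (24 adjusted over the list alone; median 1.92, adjusted p = 4.56e-46) and XBP1 and ER-associated degradation genes in 20 of 23 (20 adjusted over the list alone; median 1.97, adjusted p = 1.13e-33). The tRNA synthetases rose in 9 of 20 (11 adjusted over the list alone) and N-glycan precursor synthesis in 9 of 25 (14 adjusted over the list alone; median 0.78, adjusted p = 1.04e-09). WNT and colon stem cell genes fell in 6 of 13 and rose in 1, with the same numbers adjusted over the list alone (median -0.56, adjusted p = 0.00366). AXIN2 (-3.43 ± 0.73), CCND1 (-0.66 ± 0.14) and SOX9 (-0.85 ± 0.19) led these decreases. Further decreases were SLC22A23 (-3.11 ± 0.67, adjusted p = 0.00126; 188 labelled reads over the 4 DMSO libraries and 12 over the 4 tunicamycin libraries) and the laminin subunit LAMB1 (-3.71 ± 0.90, adjusted p = 0.00411; 106 and 4 labelled reads). In all, 1083 of 10459 genes passed (765 higher, 318 lower); with scaling by total reads 1338 passed with the split turned to 462 higher and 876 lower, and with only the 8 libraries compared 328 passed. The medians of the 3 ER stress lists stayed above 0 under every scaling tried.

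The labelled share compares labelled with unlabelled reads of the same gene, so it rises when the new part of a transcript pool grows relative to the old part. After tunicamycin in siControl it rose for ER chaperones in 18 of 20 (19 adjusted over the list alone; median 1.56, camera adjusted p = 2.02e-35), led by HSPA5 (1.49 ± 0.08, adjusted p = 4.75e-20) and the protein disulfide isomerase P4HB (1.43 ± 0.10). It also rose for XBP1 and ER-associated degradation genes in 12 of 23 (16 adjusted over the list alone; adjusted p = 2.55e-10), for tRNA synthetases in 10 of 20 (10 adjusted over the list alone) and for N-glycan precursor synthesis in 9 of 25 (12 adjusted over the list alone). PERK-ATF4 genes were mixed, 8 higher and 2 lower of 27 (11 and 3 adjusted over the list alone; adjusted p = 0.0304, and adjusted p = 0.171 with an estimated correlation). The amino acid genes ASNS (1.46 ± 0.16), SLC7A5 (1.28 ± 0.13) and PSAT1 (1.61 ± 0.20) rose and SLC3A2 fell (-0.79 ± 0.10). Immediate early genes fell in 8 of 21 (8 adjusted over the list alone; median -0.78, adjusted p = 3.02e-05), including IER3 (-0.62 ± 0.05), EGR1 (-0.88 ± 0.11) and KLF6 (-1.06 ± 0.15). In total RNA these 3 genes were higher, while the list as a whole did not pass with an estimated correlation. Lists matched on labelled share had a median share change of -0.855. They were matched on the siControl DMSO libraries, which are also the reference here, so part of their fall can come from that choice. Genes that rose included NUCB2 (2.89 ± 0.48; 4.88 ± 1.96% labelled under DMSO and 24.12 ± 5.46% under tunicamycin), SMIM14 (3.10 ± 0.66; 3.62 ± 2.63% and 20.54 ± 9.34%), NIBAN1 (3.10 ± 0.75), ACAD11 (2.76 ± 0.63) and MAP1B (2.64 ± 0.61). Calls of a decrease that rest on few labelled reads include THRA (40 over the DMSO libraries and 0 over the tunicamycin libraries; adjusted p up to 0.0764 and lost in 4 of 8 omissions, siControl tunicamycin replicate 3 among them), GALNT14 (92 and 1; adjusted p = 0.0132, and 0.0665 without siControl tunicamycin replicate 4) and IGF2 (48 and 3; adjusted p = 0.0417, up to 0.154 and lost in 6 of 8 omissions). Decreases also included SLC22A23 (-2.93 ± 0.68) and CHDH (-2.86 ± 0.64; 37.53 ± 12.4% and 6.05 ± 6.41%). In all, 787 of 10428 genes passed (484 higher, 303 lower); scaling by total reads gave 1475 with 191 higher and 1284 lower, and the 8 libraries alone gave 423.

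Under DMSO, siIGF2BP2 lowered a small set of genes beside its target. TNS4 fell by 1.47 on the log2 scale (SE 0.23, adjusted p = 0.0014) and the hypoxia-responsive NDRG1 by 1.32 (SE 0.17, adjusted p = 0.000127). Both calls, and that of IGF2BP2 (-1.60 ± 0.21, adjusted p = 0.000141), held with any 1 of the 8 libraries left out. SERPINB9 (-1.28 ± 0.24, adjusted p = 0.0103; 0.0575 without siControl DMSO replicate 3, and also lost without siIGF2BP2 DMSO replicate 4) was lower as well. So was the chromatin protein HMGA1 (-1.17 ± 0.25, adjusted p = 0.0267; up to 0.119 and lost with any 1 library left out). Ranked likewise, the largest increases were PSKH1 (1.27 ± 0.25), LMLN (1.02 ± 0.20), FAM111A (0.82 ± 0.16), EXPH5 (0.82 ± 0.18) and ANKRD33B (0.74 ± 0.16). These calls ended in 5, 4, 3, 7 and 6 of the 8 omissions. The adjusted p reached 0.095 and 0.0747 for PSKH1 and FAM111A without siControl DMSO replicate 4, 0.108 for LMLN without siIGF2BP2 DMSO replicate 3, 0.232 for EXPH5 without siIGF2BP2 DMSO replicate 1 and 0.158 for ANKRD33B without siControl DMSO replicate 2. In all, 33 genes passed (11 higher, 22 lower), 105 with DESeq2, and 19, 15, 18 and 21 without siControl DMSO replicates 2 and 3 and siIGF2BP2 DMSO replicates 1 and 4.

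After siIGF2BP3 under DMSO, 7 genes passed, 6 of them lower. IGF2BP3 (-1.54 ± 0.17, adjusted p = 7.69e-06), the Golgi GTPase RAB6A (-1.03 ± 0.12, adjusted p = 1.35e-05) and the α-tubulin TUBA1A (-0.98 ± 0.14, adjusted p = 0.000299) kept their calls with any 1 of the 8 libraries left out. PM20D2 (-1.05 ± 0.21, adjusted p = 0.0338; up to 0.251, lost with any 1 library left out) and the complement regulator CD59 (-0.66 ± 0.12, adjusted p = 0.0218; up to 0.154, lost in 6 of 8 omissions) were lower too. STARD4, a cholesterol transporter, was lower (-1.79) and the glycine transporter SLC6A9 higher (1.48). DESeq2 gave 11 genes, and the count went down to 3 (IGF2BP3, RAB6A and TUBA1A) without siControl DMSO replicate 3 or 4 or siIGF2BP3 DMSO replicate 2 or 4, and to 4 without siIGF2BP3 DMSO replicate 1. The double knockdown under DMSO also gave 7 genes, 6 of them lower. These included IGF2BP2 (-1.73 ± 0.21, adjusted p = 4.74e-05), IGF2BP3 (-1.36 ± 0.17, adjusted p = 4.74e-05) and RAB6A (-0.78 ± 0.12, adjusted p = 0.00156), which kept their calls in every omission. INSIG1, a regulator of sterol sensing (-1.05 ± 0.20, adjusted p = 0.0392; up to 0.198 and lost in 7 of 8 omissions), and SLC37A3 (-0.90 ± 0.18, adjusted p = 0.0409; up to 0.202 and lost in all 8) did not. The mitochondrial transporter ABCB6 was higher (1.04 ± 0.19, adjusted p = 0.0278; up to 0.136 and lost in 6 of 8). DESeq2 gave 33 genes and the GC correction 15; the count was 3 without siControl DMSO replicate 1, 3 or 4 or double knockdown DMSO replicate 2 or 3, and 4 without siControl DMSO replicate 2 or double knockdown DMSO replicate 4.

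Cholesterol synthesis genes were lower as a list after all 3 knockdowns under DMSO, which share the same 4 control libraries. The median log2 change of the 23 measured genes was -0.32 after siIGF2BP2 (camera adjusted p = 6.73e-08), -0.34 after siIGF2BP3 (adjusted p = 7.88e-11) and -0.20 after the double knockdown (adjusted p = 1.02e-07). In each, 1 member passed, INSIG1, STARD4 and INSIG1, and 2, 2 and 4 adjusted over the list alone. Glycolysis and hypoxia genes were lower too, with medians of -0.26, -0.20 and -0.20 (adjusted p = 0.000735, 0.0251 and 0.000135). Of 23 genes, edgeR called 1 (NDRG1), 0 and 0, and 1, 0 and 1 adjusted over the list alone. PERK-ATF4 genes were higher after siIGF2BP3 (median 0.26, adjusted p = 0.00127; 1 of 28, SLC6A9, and 1 adjusted over the list alone) and after the double knockdown (median 0.16, adjusted p = 0.00283; 2 adjusted over the list alone). Adhesion and cytoskeleton genes were lower after siIGF2BP2 (median -0.18, adjusted p = 0.00112; 0 adjusted over the list alone). By the preset correlation alone, 2 more lists were lower after siIGF2BP2. Immediate early genes had a median of -0.36 (adjusted p = 0.000137, and adjusted p = 0.0723 with an estimated correlation; EGR1 called, 1 adjusted over the list alone). ER chaperones had a median of -0.31 (adjusted p = 0.00189, and adjusted p = 0.0863 with an estimated correlation; 0 adjusted over the list alone). Reported IGF2BP target mRNAs did not pass as a list in any knockdown comparison.

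**Figure D4:**
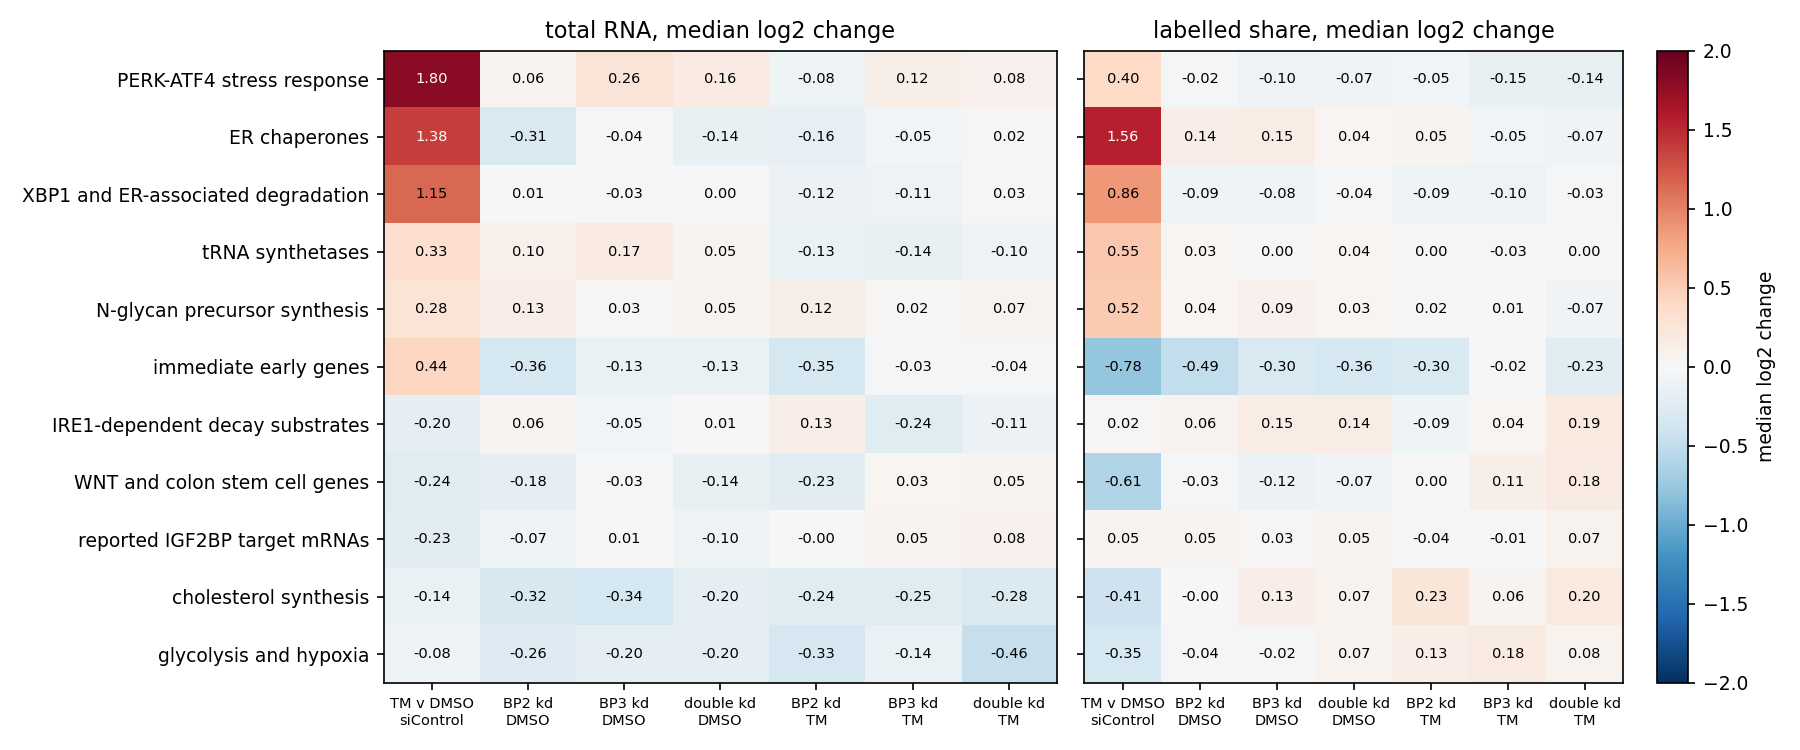
Median log2 change of 11 gene lists in total RNA (left) and labelled share (right); columns are tunicamycin (TM) against DMSO in siControl, then knockdown (kd) of IGF2BP2 (BP2), IGF2BP3 (BP3) or both against siControl under DMSO and under tunicamycin. The ER stress lists stand out after tunicamycin (PERK-ATF4 1.80, ER chaperones 1.38 in total RNA), and cholesterol synthesis is below 0 in every knockdown column of total RNA (-0.20 to -0.34).

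Under tunicamycin the knockdowns were compared with the siControl libraries that include the outlying replicate 3. After siIGF2BP2, the kinase MAPK1 fell (-1.29 ± 0.15, adjusted p = 3.22e-05) and the transporter SLC16A9 rose (1.39 ± 0.23, adjusted p = 0.0014). With IGF2BP2 (-1.71 ± 0.21, adjusted p = 4.27e-05) these kept their calls with any 1 library left out. CNTLN fell (-2.15 ± 0.43, adjusted p = 0.011; 0.0542 without siIGF2BP2 tunicamycin replicate 3), and IGFBP6 was lower (-1.68 ± 0.36, adjusted p = 0.0198), but -0.76 with adjusted p = 0.102 without siControl tunicamycin replicate 3. ZFYVE28 (-1.24 ± 0.27) turned to 0.365 when the transcript row with the longest 3′ UTR was used. It lost its call in 4 of 8 omissions, among them siControl tunicamycin replicate 3 (-0.98, adjusted p = 0.0668). After siIGF2BP3, BRD3, a bromodomain protein (-1.35 ± 0.21, adjusted p = 0.00201), and the circadian transcription factor CLOCK (0.67 ± 0.12, adjusted p = 0.00681) kept their calls with IGF2BP3 (-1.97 ± 0.17, adjusted p = 3.81e-08). The methyltransferase CARM1 (-1.57 ± 0.32, adjusted p = 0.0376) went to -0.83 with adjusted p = 0.316 without siControl tunicamycin replicate 3. After the double knockdown IGF2BP2 (-1.93 ± 0.21, adjusted p = 4.01e-06) and ZBTB20 (0.75 ± 0.13, adjusted p = 0.00405) kept their calls. The circadian gene DBP (1.01 ± 0.18, adjusted p = 0.00722) lost its call only without double knockdown tunicamycin replicate 3 (adjusted p = 0.0535). Decreases in CST6 (-2.52 ± 0.50), KLC3 (-2.15 ± 0.46), CNTLN (-1.97 ± 0.42) and KLK10 (-1.70 ± 0.37) lost their calls without siControl tunicamycin replicate 3. They went to -1.06, -1.05, -1.44 and -0.93 (adjusted p = 0.18, 0.314, 0.164 and 0.287). Glycolysis and hypoxia genes were lower after siIGF2BP2 (median -0.33, camera adjusted p = 0.00631; NDRG1 called, 4 adjusted over the list alone), a call that ended without siControl tunicamycin replicate 3 (adjusted p = 0.0693). Cholesterol synthesis genes were lower after all 3 knockdowns (medians -0.24, -0.25 and -0.28, adjusted p = 0.00191, 0.000693 and 0.00492; 2, 5 and 8 of 23 adjusted over the list alone). With an estimated correlation these were adjusted p = 0.0856, 0.103 and 0.136, and without siControl tunicamycin replicate 3 they were adjusted p = 0.0157, 8.02e-05 and 0.00169 with an estimated correlation.

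These counts depended on single libraries. With all libraries 61 genes passed after siIGF2BP2 (19 higher, 42 lower), 17 after siIGF2BP3 (4 and 13) and 87 after the double knockdown (13 and 74). On only the 8 libraries compared, edgeR called 0 in each, and DESeq2 on all libraries called 238, 918 and 1120. Without siControl tunicamycin replicate 3 the counts were 123, 9 and 39, of which 51, 7 and 26 were shared with the full set. Without siControl tunicamycin replicate 2 they were 187, 1733 and 1929, and without replicate 4 they were 117, 1352 and 1574; without replicate 1 they were 164 after siIGF2BP2 and 334 after the double knockdown. Leaving out 1 knockdown library gave as few as 31 (siIGF2BP2 replicate 2; 34 without replicate 4), 5 (siIGF2BP3 replicate 4; 7, 6 and 6 without replicates 1, 2 and 3) and 14 genes (double knockdown replicate 3; 19, 15 and 33 without replicates 1, 2 and 4).

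Changes after the knockdowns correlated across genes, which are not independent replicates, but all share 1 set of controls. Under DMSO the correlation of log2 changes was 0.476 between siIGF2BP2 and siIGF2BP3, 0.60 between siIGF2BP2 and the double knockdown and 0.513 between siIGF2BP3 and the double knockdown, against 0.497, 0.497 and 0.503 for simulated unchanged groups. With the control libraries split between the comparisons it was 0.069, 0.129 and 0.058. The covariances were 0.0881, 0.0994 and 0.0818 against 0.0502, 0.0501 and 0.0507 simulated, differences of 0.0379, 0.0493 and 0.0311. Under tunicamycin the correlations were 0.54, 0.611 and 0.814 against 0.514, 0.519 and 0.518 simulated, and -0.049, 0 and 0.162 with split controls; covariance differences were 0.0856, 0.1124 and 0.2173. Genes called in both knockdowns of a pair under DMSO were SLC6A9 (siIGF2BP2 and siIGF2BP3, higher), IGF2BP2, INSIG1 and SLC37A3 (siIGF2BP2 and double, lower) and IGF2BP3, RAB6A and TUBA1A (siIGF2BP3 and double, lower). In the simulated unchanged groups, which share controls, 0 genes were shared in each pair. Those groups were drawn gene by gene, without deviations common to many genes of a library. An excess over them, in covariance or in shared calls, is thus not shown to come from the knockdowns. With the controls split, the pairs shared on average 0.33 higher and 0 lower, 0.33 higher and 2.33 lower, and 0 higher and 1 lower. Under tunicamycin the shared calls were 3 higher and 1 lower (siIGF2BP2 and siIGF2BP3), 7 higher and 19 lower (siIGF2BP2 and double), and 3 higher and 7 lower (siIGF2BP3 and double), against 0, 0.05 and 0 in the simulated groups. With the controls split they were 0 on average, except 0.67 lower for siIGF2BP3 and the double knockdown. BRD3 and RAB6A were among those lower in that pair. CLOCK, NFIA and SGPL1 were higher after each knockdown, but after siIGF2BP3 SGPL1 (0.75 ± 0.16, adjusted p = 0.0453) went to 0.59 with adjusted p = 0.118 without siControl tunicamycin replicate 3. NFIA (0.57 ± 0.11, adjusted p = 0.0238) lost its call there without siIGF2BP3 tunicamycin replicate 1, 3 or 4 (adjusted p up to 0.121), and SGPL1 without any 1 of the 4 (up to 0.161). In no pair was a gene called in opposite directions.

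For labelled RNA after knockdown, under DMSO 0 genes passed in edgeR in any of the 3 comparisons of 10459 genes, and 2, 0 and 1 passed by DESeq2. At an unadjusted p under 0.05 there were 390, 294 and 223, fewer than the 523 that chance alone gives. Under tunicamycin 4 genes passed after siIGF2BP2 (1 higher, LAGE3 at 1.88 ± 0.36; 3 lower, CST6 at -2.79 ± 0.52, NDUFS7 at -2.36 ± 0.48 and SMURF2 at -1.10 ± 0.20). After siIGF2BP3 1 passed (BAD, -2.70 ± 0.50), and 18 after the double knockdown, all lower, led by CST6 (-2.82 ± 0.51) and GSTZ1 (-2.55 ± 0.57). Under tunicamycin 988, 1455 and 1546 genes had an unadjusted p under 0.05, more than 523, and DESeq2 called 37, 153 and 253. With counts below 523 under DMSO and above it here, the excess is not shown to come from the knockdowns. None of the named calls held with every library left out in turn. Without siControl tunicamycin replicate 3, CST6 went to -1.20 after siIGF2BP2 and -1.23 after the double knockdown (adjusted p = 0.316 and 0.717), NDUFS7 to -1.06 (adjusted p = 0.44), and BAD and GSTZ1 to adjusted p = 0.595 and 0.834. LAGE3 and SMURF2 reached adjusted p = 0.119 and 0.102 without siIGF2BP2 tunicamycin replicates 2 and 1. The counts ranged from 0 to 19, 0 to 361 and 0 to 482 with 1 library left out. Scaling by total reads gave 194, 102 and 540 genes, nearly all lower (192, 101 and 538), with all-gene medians moved by -0.34, -0.16 and -0.19.

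The labelled share of the targeted mRNAs rose after knockdown, as their unlabelled part shrank more than their labelled part. IGF2BP2 reads were 15.89 ± 1.71% labelled in siControl under DMSO, 47.03 ± 2.37% after siIGF2BP2 (log2 change of the labelled to unlabelled ratio 2.47 ± 0.17, adjusted p = 4.07e-15) and 42.43 ± 4.62% after the double knockdown (2.07 ± 0.17). IGF2BP3 reads were 22.68 ± 4.07% labelled in siControl, 53.17 ± 2.28% after siIGF2BP3 (2.06 ± 0.21, adjusted p = 6.75e-09) and 47.55 ± 10.63% after the double knockdown (1.73 ± 0.21). Several other mRNAs behaved likewise under DMSO. After siIGF2BP2 TXNRD1, thioredoxin reductase, went from 25.52 ± 3.10% to 42.80 ± 2.00% (1.35 ± 0.22, adjusted p = 0.000291). After siIGF2BP3 RAB6A went from 10.90 ± 1.79% to 25.96 ± 8.19% (1.58 ± 0.24, adjusted p = 8.65e-05), PM20D2 from 23.00 ± 3.98% to 41.60 ± 4.26% (1.36 ± 0.23, adjusted p = 0.000648) and BRD3 from 16.29 ± 3.10% to 31.69 ± 4.95% (1.36 ± 0.20, adjusted p = 8.65e-05). After the double knockdown BRD3 (1.19 ± 0.20) and HMGA1 (4.21 ± 0.23% to 5.72 ± 0.03%; 0.57 ± 0.08, adjusted p = 3.83e-05) were higher. Shares fell after siIGF2BP2 for CPEB3 (75.15 ± 12.56% to 25.90 ± 6.62%; -2.79 ± 0.50, adjusted p = 0.00162), EGR1 (-0.93 ± 0.12, adjusted p = 3.89e-07) and ID1 (-0.70 ± 0.13). They fell after siIGF2BP3 for IER3 (-0.33 ± 0.05, adjusted p = 0.000514) and after the double knockdown for ID1 (-0.72 ± 0.13) and ZFP36L1 (-0.67 ± 0.11, adjusted p = 0.000523). The calls given so far in this paragraph held with any 1 of the compared libraries left out. The genes that fell are 69.2 to 85.52% labelled in siControl under DMSO, and lists matched to the immediate early genes on labelled share had medians of -0.624, -0.412 and -0.482 in the 3 comparisons. The test against 0 thus does not show these falls to be specific to the gene, and IER3 fell by less than the matched median. The lists were matched on the siControl DMSO libraries, which are also the reference. Part of their own fall can come from that choice, so they do not decide whether a fall is specific. ZBTB5 was lower after each knockdown (-1.36 ± 0.29, -1.37 ± 0.29 and -1.40 ± 0.29, adjusted p = 0.0201, 0.0182 and 0.0152). These calls ended in 4, 5 and 4 of 8 omissions, siControl DMSO replicates 1 and 4 among them, with adjusted p up to 0.115, 0.138 and 0.168. Immediate early genes were lower as a list in all 3 (medians -0.49, -0.30 and -0.36 over 21 genes; camera adjusted p = 0.000447, 0.00506 and 0.000291). The members called were IER3 and EGR1, IER3 and DUSP5, and IER3, with 6, 4 and 4 adjusted over the list alone. The call of DUSP5 (-0.74) was lost in 4 of 8 omissions, with adjusted p up to 0.168. The overall labelling was lower in the same groups.

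In all, the share of 25 of 10428 genes (17 higher, 8 lower), 11 (6 and 5) and 12 (5 and 7) passed under DMSO after siIGF2BP2, siIGF2BP3 and the double knockdown. With 1 library left out the counts were 9 to 20, 5 to 9 and 7 to 13. Scaling by total reads gave 104 (4 higher, 100 lower) after siIGF2BP2, with the all-gene median moved by -0.23. Under tunicamycin 22 (13 and 9), 4 (3 and 1) and 7 (5 and 2) genes passed, and 1, 4 and 3 with only the 8 libraries compared. There were 637 (7 higher, 630 lower), 16 (3 and 13) and 70 (3 and 67) when scaled by total reads, which moved the all-gene medians by -0.38, -0.23 and -0.28. PM20D2 rose after siIGF2BP3 (16.87 ± 1.07% to 37.44 ± 4.38%; 1.76 ± 0.25, adjusted p = 1.93e-05) and after the double knockdown (34.26 ± 2.57%; 1.62 ± 0.24, adjusted p = 7.2e-05). RAB6A rose after siIGF2BP3 (1.42 ± 0.24, adjusted p = 0.000995) and HMGA1 after the double knockdown (0.58 ± 0.09, adjusted p = 7.2e-05). NDUFS7 (-1.42 ± 0.26, adjusted p = 0.00411) and HMGA2 (-0.70 ± 0.12, adjusted p = 0.00108) fell after siIGF2BP2 and IER3 fell after the double knockdown (-0.31 ± 0.05, adjusted p = 0.00102; lists matched on labelled share had a median of -0.143). The targeted genes rose again, IGF2BP2 by 1.74 ± 0.17 and IGF2BP3 by 1.70 ± 0.22 in their own knockdowns. These calls held with any 1 of the compared libraries left out, whereas the counts went from 6 to 21, 3 to 10 and 5 to 13. MAPK1 was higher after siIGF2BP2 (1.21 ± 0.25, adjusted p = 0.013), a call lost without siControl tunicamycin replicate 4 or siIGF2BP2 tunicamycin replicate 2 or 3 (adjusted p up to 0.124).

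Whether a knockdown changed the response to tunicamycin was tested as the interaction of the 2 factors. For total RNA edgeR called 0 genes for siIGF2BP2, 1 for siIGF2BP3 and 0 for the double knockdown, with 422, 2087 and 1452 genes at an unadjusted p under 0.05 where chance alone gives 594, and 0, 2 and 0 by DESeq2. The gene called was SNORC (-3.31), at 4 to 43 reads per library. It was not called without siControl tunicamycin replicate 3, with the GC correction or with only the groups compared. With 1 library left out the siIGF2BP3 count ranged from 0 to 482, the latter without siControl tunicamycin replicate 2. For labelled RNA edgeR called 0 in each, with 451, 1129 and 832 at an unadjusted p under 0.05 (523 by chance) and 0 by DESeq2. For the labelled share it called 0 in each, with 532, 582 and 467 (521 by chance) and 0 by DESeq2. With all libraries no gene list passed camera's test in any interaction. Without siControl tunicamycin replicate 3, an omission singled out after the data were seen, the PERK-ATF4 list passed for total RNA in all 3. Its median interaction was -0.26 for siIGF2BP2 (adjusted p = 2.62e-07), -0.18 for siIGF2BP3 (adjusted p = 0.0193) and -0.24 for the double knockdown (adjusted p = 0.000307). Of its 28 genes edgeR called 0 in each, and 2, 1 and 1 adjusted over the list alone. That smaller rise after knockdown thus rests on leaving out 1 library, and differences between control and knockdown in the number of genes called after tunicamycin, or in named genes such as CHAC1, are not shown to be differences in response.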

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

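Of the explanations weighed here, less new transcription of the immediate early genes was the one written after the values were seen. The search for outlying libraries covered 64 group values by Dixon's test at its 95% critical value, of which 6 stood out; chance gives about 1 in 20.

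Replicate 3 of siControl under tunicamycin lay far from its group in 3 values. Its 10 most abundant genes took 11.45% of its reads (5.47 to 6.19% in the others), its median correlation with the group was 0.6908 (0.8925 to 0.9222), and IGF2BP2 stood at 724.1 CPM (281.7 to 355). GAPDH stood at 53160 CPM (12108, 4907 and 6710 in replicates 1, 2 and 4) and RPL8 at 17677 CPM (4562, 2379 and 2650), while PFN1 stood at 4 CPM (138, 1138 and 732). These 3 genes were picked after their values were seen. In them replicate 1 lay part of the way towards replicate 3, and it differed from replicates 2 and 4 by a chi-square per gene of 71.92 and 54.99, against 7.27 between those 2. Lower depth does not produce this: the other 3 libraries thinned to its read number kept a median correlation among themselves of at least 0.906 (0.907 before thinning). Nor does a trend on GC content, since its correlation was 0.704 after the trend was removed, against at least 0.905 in the others. It is not a DMSO library under a tunicamycin label either, since 185 genes higher after tunicamycin in all 3 knockdowns were higher in it by a median of 1.127 (log2), against 1.299 to 1.395 in the other 3. The design gives no biological explanation, and none was tested.

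Replicate 4 of the double knockdown under tunicamycin had more reads, 13.15 against 8.38 to 8.87 (in 1e6 reads), and a lower median correlation with its group, 0.9489 against 0.9801 to 0.9826. Replicate 2 of siIGF2BP2 under DMSO had a median correlation of 0.9225 against 0.9619 to 0.9621. SNORC differed between groups by the interaction test, with a response to tunicamycin that turned after siIGF2BP3 (-3.306). In siControl it went from 0.466 to 1.43 CPM under DMSO to 3.91 to 7.81 CPM under tunicamycin, and after siIGF2BP3 from 1.81 to 5.39 CPM to 0.765 to 1.74 CPM, at 4 to 43 reads per library. The call was lost without siControl tunicamycin replicate 3, with the GC correction and with only the groups compared. Of the data the report does not use, 12551 transcript rows held reads, had no matching gene name and did not repeat the counts of a named row.

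Whether the lower labelled share of immediate early genes after knockdown under DMSO comes from the lower conversion rate of those libraries was not decided. A median of 78.5% of the reads of these genes is labelled in siControl under DMSO, against 21.3% over all genes. Of 10000 random lists matched on labelled share 80.85, 79.88 and 82.59% had a median at least as low after siIGF2BP2, siIGF2BP3 and the double knockdown. After tunicamycin in siControl 67.56% did. The prediction of a lower conversion rate was met in each. However, the matching used the siControl DMSO libraries, which are also the reference of these comparisons. Genes matched on a high share can thus fall through the choice alone. After siIGF2BP2, siIGF2BP3 and the double knockdown under tunicamycin, where the list did not pass, its medians were -0.301, -0.023 and -0.231, and 16.29, 79.76 and 21.08% of matched lists were as low. Matched medians there were -0.137, -0.136 and -0.143, against -0.624, -0.412 and -0.482 under DMSO. Yet the conversion rate was lower under tunicamycin too, at 0.687, 0.809 and 0.772% against 1.036% in siControl. The matched lists therefore cannot decide on the conversion rate. Less new transcription of the immediate early genes cannot be told from a lower conversion rate: their labelled RNA was lower by camera in 1 of the 3 knockdown comparisons under DMSO.

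Genes lower in total RNA after knockdown under DMSO, the targeted genes left out, tended to have a higher labelled share, which could mean faster loss of existing RNA. This was tested in the tunicamycin libraries, which share no library with the DMSO comparisons. Of 29 gene and knockdown pairs (25 genes) 22 had a higher share there, against 3 of 13 pairs for genes higher under DMSO. The medians there were -0.847 for total RNA and 0.593 for share. The prediction of faster loss was met with these 22 of 29 pairs. Under DMSO itself 21 of the 29 pairs had a higher share. These counts do not measure how much of the fall in total RNA comes from faster loss. Less new RNA made cannot be excluded as a part of that fall. Labelled RNA was lower as well under tunicamycin (median -0.398, against -0.847 for total RNA). Off-target effects of the siRNAs were not tested.

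Whether other splits of the same 8 libraries into 4 and 4 call as many genes was counted over all 35 splits. Each split was fitted on only the libraries compared. The real counts here are thus not those of the fits of all 32 libraries, whose calls the splits do not test. Where the real count is 0 every split reaches it, which decides nothing. For tunicamycin in siControl 1 of 35 splits reached the real count, the real split itself, for total RNA (97 genes; 0 in the best other split), labelled RNA (328; 0) and share (423; 0). Within the knockdowns the real split was the only one after siIGF2BP3 (1 of 35; 1543 genes, 0 in others) and the double knockdown (1 of 35; 733, 0), and 2 of 35 reached it after siIGF2BP2 (290; 3039 in the other). For total RNA under DMSO 2 of 35 splits reached the real counts of 32, 5 and 7 genes after siIGF2BP2, siIGF2BP3 and the double knockdown, with 926, 740 and 205 genes in the other split. Under tunicamycin the real counts were 0, so 35 of 35 reached them, and another split called 3215, 0 and 0 genes. For labelled RNA under DMSO the numbers were 3, 35 and 35 of 35 (real counts 1, 0 and 0; 71, 23 and 24 in other splits) and under tunicamycin 35 of 35 each (real counts 0; 1046, 0 and 0). For the share it was 1 of 35 after each knockdown under DMSO (17, 12 and 15 genes; 7, 1 and 4 in others), and 2, 1 and 1 of 35 under tunicamycin (1, 4 and 3 genes; 16, 0 and 1 in others). For the interactions all 100 drawn splits of total and of labelled RNA and all 30 of share reached the real count of 0, with up to 2700 genes (total RNA), 668 (labelled RNA) and 3 (share) in another split. Splits that call many genes show structure among the libraries that follows neither siRNA nor treatment.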

How the results depend on the processing

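The longest 3′ UTR row, the GC correction, the separate mention of siControl tunicamycin replicate 3 and the comparisons of tunicamycin within each knockdown were chosen after the data were seen. Below, BP2, BP3 and double stand for the knockdowns of IGF2BP2, IGF2BP3 and both against siControl, in that order, and counts are genes past the threshold. The cause of a change was not tested. Fewer libraries in a fit leave fewer degrees of freedom. That alone does not account for the changes, since some counts rose with only the groups compared. For tunicamycin after siIGF2BP3 and the double knockdown they went from 574 to 1543 and from 516 to 733. Pairs of libraries differed by a chi-square per gene of 7.27 to 287.71 in siControl under tunicamycin. After siIGF2BP3 under tunicamycin it was 6.21 to 16.65. Comparisons with siControl under tunicamycin may thus have too small standard errors in the fit of all libraries.

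Knockdown of the targeted genes held in 8 of 8 tests under every alternative but the fit of only the groups compared, where 4 held. Of the calls of named genes, those kept were 179 of 180 with size factors and 179 with DESeq2's test, 97 of 100 with the GC correction, 173 of 176 with the longest 3′ UTR row, 173 of 180 with no filter and 155 of 180 with the block. A further 99 of 172 were kept with only the groups compared, 72 of 80 with scaling by total reads and 1098 of 1440 with a library left out. Only ZFYVE28 reversed, from -1.235 to 0.365 after siIGF2BP2 under tunicamycin with the longest 3′ UTR row.

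With only the groups compared, total RNA gave 97 genes for tunicamycin in siControl (main 1588), 290 and 1543 for tunicamycin after siIGF2BP2 and siIGF2BP3 (450 and 574), 0, 0 and 0 for BP2, BP3 and double under tunicamycin (61, 17 and 87) and 0 for the BP3 interaction (1). Labelled RNA gave 328 for tunicamycin (1083), 1 for BP2 under DMSO (0) and 0, 0 and 0 under tunicamycin (4, 1 and 18). The share gave 423 for tunicamycin (787), and 1 and 3 for BP2 and double under tunicamycin (22 and 7).

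DESeq2's test gave for total RNA 105, 11 and 33 under DMSO (33, 7 and 7), 238, 918 and 1120 under tunicamycin and 2 for the BP3 interaction. For labelled RNA it gave 2 and 1 for BP2 and double under DMSO (0 and 0) and 37, 153 and 253 under tunicamycin, and for the share 34 for BP2 under tunicamycin (22). Size factors gave 221 for double under tunicamycin (87), 11 for labelled RNA of BP2 (4) and 7 for the share of BP3 under tunicamycin (4). With no filter, double under tunicamycin gave 55 (87), labelled RNA of BP3 and double under tunicamycin 41 and 117. The share gave 45 and 17 for BP2 and BP3 under DMSO (25 and 11), 55, 33 and 23 under tunicamycin (22, 4 and 7) and 3, 9 and 5 for the interactions (0 each). The GC correction gave for total RNA 15 for double under DMSO (7), 117 for BP2 under tunicamycin (61) and 0 for the BP3 interaction (1). The longest 3′ UTR row gave 10 for labelled RNA of BP2 under tunicamycin (4).

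Scaling by total reads gave for labelled RNA 1 for BP2 under DMSO and 194, 102 and 540 under tunicamycin, and for the share 1475 for tunicamycin, 104 for BP2 under DMSO and 637, 16 and 70 under tunicamycin. With the replicate number as a block total RNA gave 7 and 31 for BP3 and double under tunicamycin (17 and 87), and labelled RNA 1 for BP2 under DMSO and 1, 0 and 0 under tunicamycin. It changed no other count by over 1.5 times. The main fits did not use the replicate number. Same-numbered libraries correlated above 0.1 throughout in only 2 comparisons, and there too pairing by number was not established.

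With 1 library left out total RNA gave 818 to 2685 for tunicamycin in siControl, 345 to 499 after siIGF2BP3, 15 to 27, 3 to 6 and 3 to 5 for BP2, BP3 and double under DMSO, 31 to 187, 5 to 1733 and 14 to 1929 under tunicamycin, and 0 to 482 for the BP3 interaction. Labelled RNA gave 0 to 19, 0 to 361 and 0 to 482 under tunicamycin. The share gave 9 to 20, 5 to 9 and 7 to 13 under DMSO and 6 to 21, 3 to 10 and 5 to 13 under tunicamycin. The difference in labelled reads ranged from -2.098 to -1.421 points.

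Of the list calls, 89 stood with the preset correlation and 46 with an estimated one. Correlations between knockdowns with the controls split were 0.069, 0.129 and 0.058 under DMSO and -0.049, 0.0 and 0.162 under tunicamycin, against 0.476, 0.6 and 0.513 and 0.54, 0.611 and 0.814 with shared controls. Splitting also leaves 2 controls per comparison. A log2 change of 1 was recovered in 46.5 to 51.5% of simulated genes for labelled RNA, the lowest of the 3 measures; depth as the cause was not tested.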

Other observations

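The labelled percent of 4 mRNAs is given here over all knockdowns under DMSO, as values (mean ± SD, n = 4); the genes were picked after their values were seen. RAB6A was 10.90 ± 1.79% labelled in siControl, 11.14 ± 2.50% after siIGF2BP2, 25.96 ± 8.19% after siIGF2BP3 and 18.50 ± 2.13% after the double knockdown. PM20D2 followed the same order at 23.00 ± 3.98, 25.98 ± 2.85, 41.60 ± 4.26 and 34.79 ± 4.33%, and BRD3 at 16.29 ± 3.10, 16.64 ± 1.08, 31.69 ± 4.95 and 29.03 ± 4.77%. HMGA1, a reported IGF2BP target, had the other order, at 4.21 ± 0.23, 6.52 ± 0.84, 4.02 ± 0.24 and 5.72 ± 0.03%, and its share was higher after siIGF2BP2 (0.89 ± 0.08, adjusted p = 1.3e-10). Differences between the knockdowns themselves were not tested.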
